A study of Bos taurus with 8 samples.

How the data were processed

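Gene expression was measured in granulosa cells of Holstein Friesian cows around the surge of luteinizing hormone (LH). Per the labels, the cows had been stimulated with FSH, the surge was induced with GnRH, and the ovaries came from a group sampled 2 h before the surge and from groups sampled 6 h and 22 h after it, which is 8 h and 24 h after GnRH. The cells were scraped from opened follicles after removal of the oocyte with its cumulus, and the labels' protocols describe them as mainly mural granulosa cells with a minor admixture of theca cells, detected by PCR for the theca gene CYP17. Each of 8 2-colour arrays carried RNA of 1 biological replicate taken after the surge and RNA of 1 replicate taken before it. The 6 h RNA was on 4 arrays of 1 slide and the 22 h RNA on 4 arrays of the other slide. On 2 of the 4 arrays of each time the post-LH RNA was in Cy5, and on the other 2 it was in Cy3. The series' design text gives 4 biological replicates per time point, so by that count pre-LH replicates were used on more than 1 of the 8 arrays. The main fit does not model such reuse. The labels number the replicates 1 to 4 but say neither whether pre-LH RNA of the same number is the same sample on both slides nor how many animals made up a replicate.

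Per the labels' protocols, the RNA was amplified as antisense RNA and labelled chemically with Cy3 and Cy5. The deposited scanner files held raw spot and local background intensity values for both dyes, with no normalization, per the file headers. The authors' deposited table of processed values held log2 ratios, 1 per probe and array; the steps behind it are not given in the sources used here. Set against the scanner values of the same array, these ratios correlated with post-LH over pre-LH with r from 0.84 to 0.93 over probes, had slopes of 0.98 to 1.08 on the log2 scale and medians from -0.016 to 0.00502, so they were read as log2 ratios, already turned for the dye swaps and centred near 0. They served only as an alternative source of values.

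From the scanner files, 45212 spots were read per array, of which 1418 were controls and 43794 were probes. Background was corrected with normexp and an offset of 50, and log2 ratios were normalised within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. A probe was tested when its mean spot intensity exceeded the 95th percentile of the 153 negative control spots on a share of at least 0.5 of the arrays of at least 1 of the 3 groups of RNA, which left 38453 probes. No spot was removed for saturation. Symbols came from the platform annotation, updated through the reference gene table. Of the 43794 probes, 21790 had 1 symbol, 22004 had none and 0 had several; 1524 symbols were updated and 99.1% of the symbols were in the reference table. The tested probes named 14138 genes, and the value of a gene was that of its brightest tested probe. Among 3582 genes with several tested probes, 14 had probes called in both directions at 6 h, 11 at 22 h and 4 between the times. The further probes of a named gene did not always pass. Only 1 probe passed, for example, of 3 for BMPR1B and of 2 for PPP2R2B at 6 h. The same was seen of 3 for NR5A2 and of 2 for FOS and IL6 at 22 h, and of 2 for HS3ST5 between the times. No genome was used, so no coordinates are given.

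The log2 ratios of all 8 arrays entered 1 linear model (lmFit, eBayes) with a common dye effect, a 6 h coefficient and a 22 h coefficient. This left 5 residual degrees of freedom and gave a prior of 1.94. The comparisons were 6 h against pre-LH, 22 h against pre-LH, and the difference between these changes. P-values were adjusted by Benjamini-Hochberg over all tested probes with a threshold of 0.05, and those in the report are limma's adjusted values unless another test is named. The dye effect passed the threshold for 2896 probes. A gene went back when its 6 h change and its later difference passed with opposite signs, and it went on when they passed with the same sign. It was late when its 22 h change and its difference between the times passed with the same sign and the unadjusted p at 6 h was 0.05 or more. A fold given as "at least" compares means of normalised log2 channel values after loess and Aquantile. There, a saturated group stands at its measured mean, and a group not above background on any array stands, per array, at the higher of its own value and the lowest value of a detected probe.

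The design, the alternatives planned and 25 lists of genes were fixed before the data were examined. The 17 process lists were ovulatory mediators and progesterone receptor targets, immediate early transcription factors, steroidogenesis, cholesterol synthesis and uptake, FSH-dependent genes of growing follicles, DNA replication and mitosis, cell cycle inhibitors, extracellular matrix, proteases and their inhibitors, prostaglandin synthesis and signalling, inflammatory cytokines and NF-kB, angiogenic and hypoxia-responsive genes, glycolysis, the unfolded protein response and amino acid stress, heat shock, apoptosis, and G protein and cAMP signalling. The 8 cell type lists held markers of theca, fibroblasts and smooth muscle, endothelium, leukocytes, erythrocytes, oocytes, ovarian surface epithelium and granulosa cells. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. Camera asks whether a list's genes stand apart from other genes; fry asks whether they move on balance one way.

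The rule for named genes took, for each comparison, the 6 largest rises and the 6 largest falls among genes past the threshold. For the comparisons with pre-LH their sign had to be the same on all 4 arrays, and between the times all 4 arrays of one time had to lie above all 4 of the other. It added the 2 members with the smallest adjusted p of each list, among those that passed, and for 22 h against 6 h only from lists that camera called. Genes with a bare accession or LOC number as symbol were passed over. PGR, PTGS2, STAR, CYP11A1, CYP19A1, LHCGR, FSHR and CYP17A1 were given whatever their result. Further genes were named in the text where a count was 5 or fewer where markers of a cell type are set out one by one, or as examples of a list, and these were chosen after their values were seen: ADORA2B, ALG5, ALG6, ALG8, AMH, ANGPT1, ANGPT2, BAX, BCL2L11, BID, BIRC3, BTG1, CD163, CDKN1A, CDKN2D, CXCL12, CYCS, EMCN, ENO2, FGF1, GADD45A, GADD45B, GJA1, HSPH1, IGF1R, INHBA, INSL3, KDM1A, KDM5B, LAMB1, LIPA, MCM2, MMP2, MYC, NID1, NR2F2, PECAM1, PPARG, PTCH1, PTGES, PTGIR, PTGIS, RAD21, RAD50, RAD51B, RAD54B, RBL2, RGS3, SEL1L, SLCO2A1, SPARC, SRSF10, SRSF2, TCF21, TIMP3, VCAN, VPS16 and VPS35. A gene that the rule named for one comparison was also given for others.

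The check on pairing asked whether arrays of the same number deviate together. Deviations of the log2 ratios from the group means correlated across slides with r of 0.33, 0.53, 0.41 and 0.22 for numbers 1 to 4, over probes. The highest r with another number was 0.23, 0.11, 0.19 and 0.33, so number 4 at 6 h correlated more with another number than with its own. The rule set for pairing asked only that every r of equal numbers lie above 0.1. This held, so the numbers were taken to pair the arrays, and a fit with the number as a block was among the alternatives tried. Arrays of equal number also had the same dye orientation, and the dye effect was not taken out of these deviations. The highest r with another number was always that of the same dye orientation, and it too lay above 0.1. The rule therefore could not tell pairing from dye orientation. With the dye effect in the model, the consensus correlation within numbers was 0.0539.

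Simulated intensities with known changes, built for all 43794 probes, were used to test the procedure. It called 74% of probes changed by 0.5 on the log2 scale at 6 h, 92% at 22 h and 45% between the times, and 100% of those changed by 1 or 2 in each comparison. Unchanged probes made up 2.6%, 4.39% and 3.09% of the calls in the same order. Changes were planted in a small share of the probes only, all above a set brightness. Noise had the same spread for every probe, and no pre-LH RNA was shared. These percentages were therefore not measured for dim probes, or for data with as many changes as were called here. The number of arrays limits the precision of every value. Median spot intensities lay between 150 and 192 in Cy3 and between 79.7 and 102 in Cy5, and the negative controls' medians between 105 and 145 and between 57.8 and 75.9.

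Alternatives set before the data were examined changed the background correction, the normalization, the filter on dim probes, the probe that stands for a gene, the dye effect, the arrays in the fit, the block, the use of separate channels, the variance model, array weights, the threshold and the source of values, and left out each array in turn. Added after seeing the data were a background from the negative controls, the median pixel intensity of a spot, a fit without both arrays of number 4, and a fit without the 3 arrays on which normexp had estimated its lowest backgrounds, -141 for replicate 3 of 6 h and -173 and -174 for replicates 1 and 2 of 22 h. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.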

Results

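Granulosa cells line the ovarian follicle and receive the surge of LH that starts ovulation. RNA of these cells, taken 2 h before the surge and 6 h and 22 h after it, was compared on 8 2-colour arrays. Each array set 1 biological replicate taken after the surge against 1 taken before it, with 4 arrays for 6 h and 4 for 22 h. The pre-LH cells came from follicles of 6 to 8 mm, the 6 h cells from follicles above 8 mm and the 22 h cells from pre-ovulatory follicles, so follicle size changed together with time. The series' design text gives 4 biological replicates per time point, and pre-LH RNA was on all 8 arrays. By that count, pre-LH replicates were used on more than 1 array. Whether the same replicate number means the same pre-LH RNA at both times is not stated in the sources used here. Between 75.1% and 85.4% of probes were detected per channel. Over the tested probes, which are not independent replicates, the log2 ratios of 2 arrays correlated with r of 0.55 to 0.87 within 6 h, 0.52 to 0.73 within 22 h and 0.13 to 0.44 between the times. Changes are given below as log2 ± SE (n = 4 arrays per time), and "rose" and "fell" are used for adjusted p under 0.05. The SE is limma's moderated value from the fit of all 8 arrays with a dye effect. A gene therefore has the same SE at 6 h and 22 h, and the SE does not show the spread of the 4 arrays. For ANPEP at 6 h it was 0.16, while the SD of the 4 arrays was 0.75.

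The first comparison asked how the cells differed from their pre-LH state 6 h after the surge. Among genes of the ovulatory response, PGR, the progesterone receptor needed for follicle rupture, rose by 3.32 ± 0.04. EGR1, an immediate early transcription factor, rose by 3.46 ± 0.13. PTX3, a protein of the hyaluronan matrix that forms around the oocyte, rose by 4.11 ± 0.16. TNFAIP6, which cross-links that matrix, was saturated after LH on all 4 arrays and was at least 27.3-fold higher (adjusted p = 0.000589). CYP19A1, the aromatase that makes estradiol in the growing follicle (-1.74 ± 0.27), and TK1, a thymidine kinase of dividing cells (-0.94 ± 0.09), fell. IDI1, an enzyme of the isoprenoid part of cholesterol synthesis, rose by 1.41 ± 0.05. In all, 3437 of 14138 genes changed, of which 1629 rose and 1808 fell, and 594 changed at least 2-fold, 339 up and 255 down.

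The largest rises at 6 h were those of GPAT3, an acyltransferase of triglyceride synthesis (4.90 ± 0.10, adjusted p = 1.84e-06), SLC39A8, a zinc and manganese importer (4.82 ± 0.16), PTX3, LYPD1 (4.01 ± 0.29) and NDP, a ligand of Wnt receptors (3.54 ± 0.31), with TNFAIP6, whose rank is not known because of its saturation. The largest falls were those of TRIB2, a pseudokinase (-3.01 ± 0.06, adjusted p = 1.77e-06), SLC35G1 (-2.96 ± 0.17), HPGD, the enzyme that inactivates prostaglandins (-2.88 ± 0.22), PPP2R2B, a regulatory subunit of protein phosphatase 2A (-2.52 ± 0.25), PLIN5, a lipid droplet protein (-2.34 ± 0.21), and MGARP, a mitochondrial protein (-2.09 ± 0.26). PPP2R2B after LH and NDP before LH were above background on only 3 of 4 arrays, so the sizes of these changes are uncertain.

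Of 27 tested ovulatory mediators and progesterone receptor targets, 16 rose and 1 fell at 6 h (18 and 1 adjusted over the list alone). The median was 0.70 (camera adjusted p = 1.79e-08; adjusted p = 0.138 with an estimated correlation). RGS2, a brake on G protein signalling, rose by 3.46 ± 0.14 and PLAT, the tissue plasminogen activator, by 2.15 ± 0.10. The member that fell was PPARG, a nuclear receptor of lipid metabolism (-1.17). PTGS2, the inducible enzyme of prostaglandin synthesis, was not above background before LH on any of the 4 arrays, and at 6 h it was on 3 of 4. Its change of 0.27 ± 0.26 did not pass (adjusted p = 0.585), with single arrays from 0.002 to 0.678. The size of this change is not known, since the pre-LH level was below background. With the authors' deposited processed values PTGS2 passed, at 0.53 (adjusted p = 0.026). Of 22 immediate early transcription factors, 14 rose and 1 fell (17 and 1 adjusted over the list alone). The median was 0.79 (camera adjusted p = 4.56e-08; adjusted p = 0.138 with an estimated correlation). BTG2, an antiproliferative factor, rose by 1.96 ± 0.06, and MYC, which drives growth and division, fell (-0.71). Of 25 proteases and inhibitors, 11 rose and 0 fell (15 and 2 adjusted over the list alone; camera adjusted p = 0.000136; adjusted p = 0.138 with an estimated correlation). They included TIMP1, an inhibitor of matrix metalloproteinases (2.57 ± 0.12). Of 20 genes of G protein and cAMP signalling, 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.00477; adjusted p = 0.138 with an estimated correlation). SPRY2, which restrains growth factor signalling, rose by 1.93 ± 0.05. The members that fell were PRKAR2B, a regulatory subunit of protein kinase A (-0.53 ± 0.05), and RGS3 (-0.25).

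Cholesterol genes rose at 6 h in 14 of 26 cases and fell in 1 (16 and 2 adjusted over the list alone). The median was 0.48 (camera adjusted p = 4.86e-06; adjusted p = 0.148 with an estimated correlation). SCARB1, the receptor that takes up cholesterol from HDL, rose by 2.09 ± 0.16, NSDHL, a sterol dehydrogenase, by 1.01 ± 0.07, and LIPA, the lysosomal lipase, fell (-0.67). Of 20 genes of the unfolded protein response, 11 rose and 0 fell (12 and 0 adjusted over the list alone). The median was 0.51 (camera adjusted p = 6.39e-06; adjusted p = 0.138 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, rose by 1.18 and HERPUD1, a factor of the degradation of misfolded proteins, by 0.81 ± 0.10. Of 26 inflammatory genes, 7 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.0219; adjusted p = 0.198 with an estimated correlation). NFKB1, a subunit of NF-kB, rose by 0.75 ± 0.11, and the chemokine CXCL12 fell (-0.68). The inflammatory list did not pass without replicate 1 of 6 h (adjusted p = 0.0608) or without the 3 arrays of the lowest background estimates (adjusted p = 0.0557).

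DNA replication and mitosis genes fell at 6 h in 27 of 42 cases and rose in 1 (35 and 1 adjusted over the list alone). The median was -0.645 (camera adjusted p = 3.26e-11; adjusted p = 0.233 with an estimated correlation). CENPF, a kinetochore protein, fell (-0.76 ± 0.07). The member that rose was MCM2, a part of the replicative helicase (0.29). Among cell cycle inhibitors, 4 of 12 rose and 3 fell (6 and 3 adjusted over the list alone), and the list did not stand apart (camera adjusted p = 0.431). Fry called it up (adjusted p = 0.000257). CDKN2B, an inhibitor of the kinases of G1 phase, rose by 3.44 ± 0.20. CDKN1A (1.28), GADD45A (0.88) and BTG1 (0.87) rose as well. CDKN2C (-0.79 ± 0.11), GADD45B (-0.86) and RBL2 (-0.46) fell.

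FSH-dependent genes of growing follicles fell at 6 h in 13 of 29 cases and rose in 2 (14 and 2 adjusted over the list alone). The median was -0.23 (camera adjusted p = 0.0256; adjusted p = 0.148 with an estimated correlation). Without replicate 1 of 6 h this list no longer passed (adjusted p = 0.0608). FSHR, the FSH receptor, fell (-0.91 ± 0.14), as did LHCGR, the LH receptor (-0.69 ± 0.09), and BMPR1B, a receptor of bone morphogenetic proteins (-0.90 ± 0.07). After LH, LHCGR was above background on only 3 of 4 arrays, so the size of its fall is uncertain. GJA1, a gap junction protein (0.71), and IGF1R (0.44) rose. Among steroidogenesis genes 2 of 19 rose, SCARB1 and HSD17B7 (0.82 ± 0.06), and 7 fell (3 and 10 adjusted over the list alone; camera adjusted p = 0.0912). Fry called this list down (adjusted p = 0.00391). STAR, which carries cholesterol into mitochondria, fell (-0.47 ± 0.11, adjusted p = 0.0285). Of its 3 probes 1 was called in the other direction. Without each of the 4 arrays of 6 h in turn it did not pass (adjusted p = 0.0608 to 0.116). CYP11A1, which makes pregnenolone from cholesterol, was at -0.67 ± 0.21 and did not pass (adjusted p = 0.0723). With the authors' deposited processed values it passed at -0.81 (adjusted p = 0.0104). Granulosa markers fell in 6 of 12 cases and rose in 1, MRO (2.30 ± 0.17) (7 and 1 adjusted over the list alone). The median was -0.58 (camera adjusted p = 0.00695; adjusted p = 0.296 with an estimated correlation). GATM, which makes a precursor of creatine, fell by 1.79 ± 0.13 on the log2 scale. Theca markers, whose cells can be scraped off with granulosa cells, had a median of -0.62 (camera adjusted p = 0.0236; adjusted p = 0.345 with an estimated correlation; adjusted p = 0.0706 without replicate 1 of 6 h and 0.0557 without the 3 arrays of the lowest background estimates). Of 8 tested, COLEC11 (-1.37 ± 0.03), ANPEP (-1.26 ± 0.16), TCF21 (-1.23) and NR2F2 (-0.69) fell and CYP17A1, the enzyme of androgen synthesis, rose by 0.36 ± 0.08 (5 and 1 adjusted over the list alone). CYP17A1 stood at 0.32, 0.34 and 0.31 without replicate 2, 3 or 4 of 6 h and did not pass (adjusted p = 0.121, 0.0899 and 0.103). Nor did it pass in 5 further alternatives, among them median centring (0.279, adjusted p = 0.798) and a background from negative controls (0.333, adjusted p = 0.427).

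Further process lists did not pass camera at 6 h. Fry called up the matrix (adjusted p = 0.0146), angiogenic (adjusted p = 0.000257), heat shock (adjusted p = 0.00281) and apoptosis lists (adjusted p = 1.6e-05). It called the prostaglandin list down (adjusted p = 0.0064) and did not call glycolysis (adjusted p = 0.0661). Of 20 matrix genes, 7 rose and 3 fell (9 and 4 adjusted over the list alone; adjusted p = 0.0976). SDC4, a heparan sulfate proteoglycan, was up by 3.15 ± 0.27, and SPARC (-0.45), LAMB1 (-0.69) and VCAN (-0.49) were lower. Of 17 prostaglandin genes, PTGIS rose (0.75) and HPGD, PTGS1 (-0.58 ± 0.09) and PTGIR (-0.31) fell (1 and 3 adjusted over the list alone; adjusted p = 0.705), with a list median of 0.03 and a mean of -0.14. Of 19 angiogenic and hypoxia-responsive genes, 6 rose and 2 fell (7 and 3 adjusted over the list alone; adjusted p = 0.0851). FGF2, a growth factor for vessels, was up by 1.73 ± 0.08, and ANGPT2 (-0.58) and FGF1 (-0.27) were lower. Of 19 glycolysis genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.24). HK2, a hexokinase, rose by 2.74 ± 0.16, and PFKM, a phosphofructokinase (-1.87 ± 0.09), and SLC16A3, the lactate exporter (-0.88), fell. Of 11 heat shock genes, BAG3 (0.84 ± 0.08), HSPE1 (0.40 ± 0.07) and HSPH1 (0.79) rose and HSPB1 (-0.40) fell (3 and 1 adjusted over the list alone; adjusted p = 0.0615; adjusted p = 0.0345 without replicate 2 of 6 h). Of 15 apoptosis genes, MCL1, which protects from cell death (1.75 ± 0.06), APAF1 (0.89 ± 0.05), BIRC3 (0.58) and CYCS (0.54) rose and BAX fell (-0.31). This gave 5 and 1 adjusted over the list alone and a camera adjusted p = 0.243. This list's median was -0.01 and its mean 0.23.

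Markers of other cells did not pass camera at 6 h. Of 15 fibroblast and smooth muscle markers, FBLN1, a matrix protein, rose (0.89 ± 0.07) and 0 fell. The median was -0.10 (1 and 0 adjusted over the list alone; adjusted p = 0.527). Of 14 endothelial markers, ENG rose (0.25 ± 0.05) and CLDN5, a tight junction protein, fell (-0.75 ± 0.10). The median was 0.07 (1 and 1 adjusted over the list alone; adjusted p = 0.492). ENG did not pass without replicate 1 or 2 of 6 h (adjusted p = 0.0532 and 0.0756) or with the deposited processed values (adjusted p = 0.0857). Of 22 leukocyte markers, CD68, a macrophage protein (0.40 ± 0.07), CD163 (0.37) and AIF1 (0.22 ± 0.05) rose. The median was 0.06 (3 and 0 adjusted over the list alone; adjusted p = 0.133). AIF1 did not pass without each of the 4 arrays of 6 h in turn (adjusted p = 0.0519 to 0.11) or with the deposited processed values (adjusted p = 0.0567). Of 8 markers of surface epithelium, the keratins KRT18 (1.11 ± 0.14) and KRT8 (2.82-fold) rose and KRT19 fell (-0.74) (2 and 3 adjusted over the list alone; adjusted p = 0.813). Of 13 oocyte markers, DAZL, an RNA-binding protein of germ cells, rose (0.46 ± 0.06) and ZAR1L fell (-0.23 ± 0.06) (1 and 1 adjusted over the list alone; adjusted p = 0.838). Of 7 erythrocyte markers AHSP fell (-0.27 ± 0.07) (0 and 1 adjusted over the list alone; adjusted p = 0.598). Mean log2 intensities were 6.91 to 7.87 for the oocyte and 6.98 to 7.58 for the erythrocyte markers. These markers were thus dim and say little about such cells. Many leukocyte markers were as dim, such as CSF1R (7.01), CD3D (7.39) and C1QC (7.41), and lack of calls among them says little too. ZAR1L did not pass without replicate 1, 2 or 4 of 6 h (adjusted p = 0.119, 0.159 and 0.125) or replicate 2 or 3 of 22 h (adjusted p = 0.0544 and 0.0636). AHSP did not pass without replicate 1, 2 or 4 of 6 h (adjusted p = 0.152, 0.149 and 0.148), without replicate 2 of 22 h (adjusted p = 0.0603) or with the deposited processed values (adjusted p = 0.0966). At an unadjusted p under 0.05 in limma, 2 proteases, 0 genes of the unfolded protein response, 2 fibroblast markers and 1 leukocyte marker were lower and 1 erythrocyte marker was higher, where the counts above are 0. The count of changed genes was 85 with median centring in place of loess, 2103 with a background from negative controls, 1967 without replicate 1 of 6 h and 1933 without replicate 2.

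**Figure D1:**
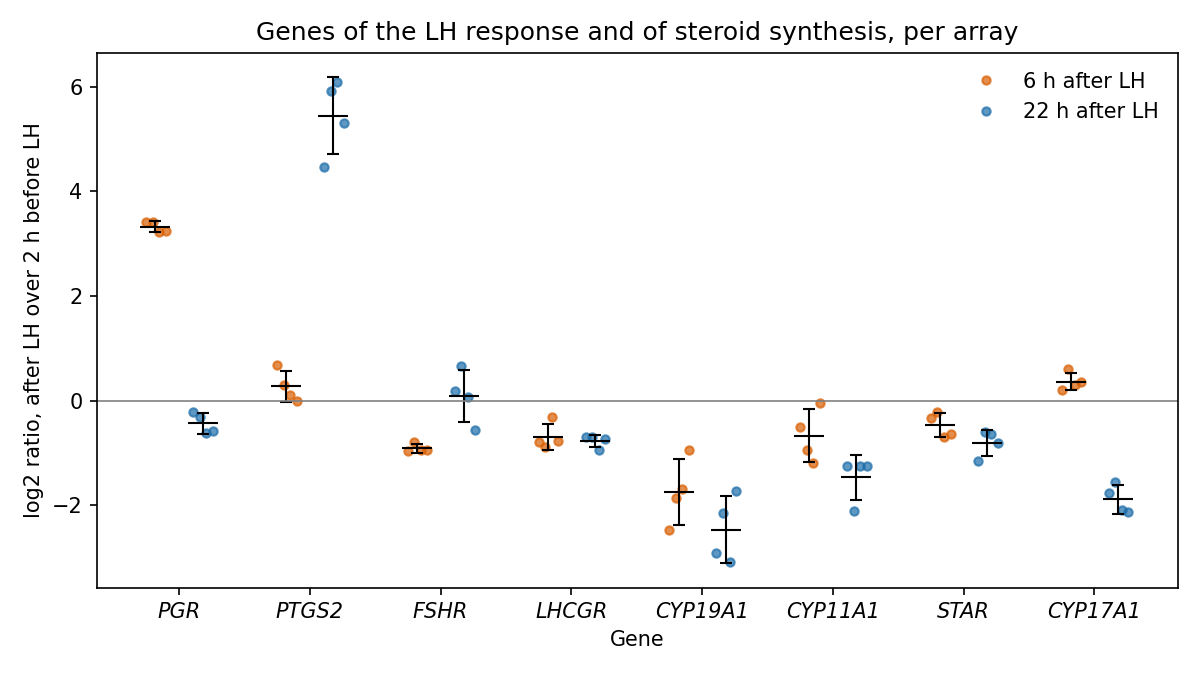
Log2 ratio of post-LH over pre-LH RNA (vertical axis) for 8 genes set in advance, with 1 point per array, orange at 6 h and blue at 22 h, and bars for the mean ± SD of 4 arrays. PGR stood at 3.32 ± 0.10 (SD, n = 4) at 6 h and -0.44 ± 0.20 at 22 h, and PTGS2 at 5.44 ± 0.73 at 22 h. At 6 h the pre-LH level of PTGS2 was not above background on any of the 4 arrays.

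The second comparison asked how the cells differed from their pre-LH state 22 h after the surge, shortly before ovulation. PTGS2 was higher by 5.44 ± 0.26, and RGS2 (4.59 ± 0.14), PTX3 (4.92 ± 0.16) and VNN2, an enzyme of the pantetheinase family (4.66 ± 0.07), rose as well. PGR was now lower (-0.44 ± 0.04). HMGCS1, an early enzyme of cholesterol synthesis, fell (-2.07 ± 0.09), and SLC2A3, a glucose transporter, rose by 1.45 ± 0.12. In all, 2878 genes changed, 1379 up and 1499 down, and 596 changed at least 2-fold, 313 up and 283 down.

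After PTGS2, the largest rises at 22 h were those of NUDT11, a phosphohydrolase of inositol pyrophosphates (5.32 ± 0.21), PTX3, TNFAIP6 (4.66 ± 0.42, saturated after LH on 2 of 4 arrays, which entered at their measured value, so that its rank is not known), VNN2 and RGS2. The largest falls were those of LRP8, a receptor of the LDL receptor family (-4.93 ± 0.20, adjusted p = 3.83e-05), CXCL14, a chemokine (-3.80 ± 0.15), INHBB, a subunit of activin and inhibin (-3.80 ± 0.23), ATP4B, a subunit of the gastric proton pump (-2.99 ± 0.10), HPGD (-2.97 ± 0.22) and TRIB2 (-2.95 ± 0.06).

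Of 27 ovulatory mediators, 14 rose and 1, PGR, fell at 22 h (15 and 1 adjusted over the list alone). The median was 0.33 (camera adjusted p = 5.33e-08; adjusted p = 0.118 with an estimated correlation). Of 22 immediate early factors, 13 rose and 1, MYC, fell (16 and 1 adjusted over the list alone). The median was 0.95 (camera adjusted p = 5.38e-09; adjusted p = 0.116 with an estimated correlation). FOS, a part of the AP-1 factor, rose by 2.40 ± 0.12 and BTG2 by 1.53 ± 0.06. Of 25 proteases and inhibitors, 8 rose and 2, TIMP3 (-0.41) and MMP2 (-0.39), fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.0136; adjusted p = 0.25 with an estimated correlation). PLAT was up by 2.54 ± 0.10 and TIMP1 by 2.22 ± 0.12. PLA2G4A, the phospholipase that releases arachidonic acid for prostaglandins, rose by 3.43 ± 0.14. With it, PTGS2 and PTGES (0.31) made 3 of 17 prostaglandin genes that rose, and HPGD, PTGS1 (-0.39) and the prostaglandin transporter SLCO2A1 (-0.79) fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.915). This list's median was -0.02, its mean 0.31, and fry called it up (adjusted p = 0.00145).

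Cholesterol genes fell at 22 h in 16 of 26 cases and rose in 1, SCARB1 (0.71) (16 and 3 adjusted over the list alone). The median was -0.79 (camera adjusted p = 9.79e-09; adjusted p = 0.116 with an estimated correlation). IDI1 fell (-1.49 ± 0.05), as did NSDHL (-1.72). DNA replication and mitosis genes fell in 34 of 42 cases and rose in 1, MCM2 (0.29) (38 and 1 adjusted over the list alone). The median was -1.14 (camera adjusted p = 4.33e-19; adjusted p = 0.189 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell (-1.94 ± 0.12), as did CENPF (-1.34 ± 0.07). Of 12 cell cycle inhibitors, CDKN2B (1.93 ± 0.20), CDKN1A (1.05), RBL2 (0.85) and CDKN2D (0.46) rose and GADD45G (-0.86 ± 0.07) and CDKN2C (-0.69) fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.69). Fry called the cell cycle inhibitors up (adjusted p = 0.00803). Glycolysis genes rose in 11 of 19 cases and fell in 1, PFKM (-0.76) (14 and 1 adjusted over the list alone). The median was 0.76 (camera adjusted p = 4.28e-05; adjusted p = 0.116 with an estimated correlation). SLC2A1, the main glucose transporter of many cells, rose by 1.53 ± 0.14 and SLC16A3 by 1.36. Of 19 angiogenic and hypoxia-responsive genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.0136; adjusted p = 0.118 with an estimated correlation). KDM3A, a histone demethylase, was up by 0.71 ± 0.06 and ANGPT1, a ligand of endothelial cells, by 1.44. Without the 3 arrays of the lowest background estimates this list no longer passed (median 0.129, adjusted p = 0.0754). Of 14 endothelial markers, set out below, 5 fell on the same arrays.

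FSH-dependent genes of growing follicles fell at 22 h in 10 of 29 cases and rose in 1, NR5A2, a nuclear receptor of steroid-making cells (1.34 ± 0.11) (12 and 1 adjusted over the list alone; camera adjusted p = 0.00501; adjusted p = 0.116 with an estimated correlation). Of the 3 tested probes of NR5A2, only 1 passed. LHCGR fell (-0.77 ± 0.09), to a dim mean log2 level of 7.30. FSHR was at 0.09 ± 0.14 and did not pass (adjusted p = 0.751), with a value of -0.07 without replicate 2 of 22 h. Of 19 steroidogenesis genes, 6 rose and 6 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.963), with a list median of 0.06 and a mean of -0.16. CYP19A1 (-2.47 ± 0.27), CYP11A1 (-1.47 ± 0.21) and STAR (-0.80 ± 0.11) fell. Granulosa markers MRO (3.53 ± 0.17) and NR5A2 rose, and CYP19A1, AMH (-1.01) and INHBA (-1.95) fell, out of 12 (2 and 4 adjusted over the list alone; camera adjusted p = 0.452). Theca markers had a median of -1.16 (camera adjusted p = 0.00029; adjusted p = 0.231 with an estimated correlation). Of 8 tested, COLEC11 (-2.55 ± 0.03), CYP17A1 (-1.88 ± 0.08), ANPEP (-1.36), TCF21 (-1.19), INSL3, a peptide hormone of theca cells (-1.14), and NR2F2 (-0.67) fell, and PTCH1, the receptor of hedgehog ligands, rose by 1.53 (6 and 1 adjusted over the list alone).

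Markers of endothelium fell at 22 h in 5 of 14 cases and rose in 0 (5 and 0 adjusted over the list alone). The median was -0.135 (camera adjusted p = 0.0265; adjusted p = 0.596 with an estimated correlation). The 5 that fell were KDR, a receptor of VEGF (-1.15 ± 0.15), EMCN (-0.48), ENG (-0.25), PECAM1 (-0.23) and TIE1 (-0.18 ± 0.03). The list did not pass without replicate 2 or 3 of 22 h (adjusted p = 0.107 and 0.0567), with the deposited processed values (adjusted p = 0.0599) or without the 3 arrays of the lowest background estimates (adjusted p = 0.0958). Without those 3 arrays KDR stood at -0.729 and did not pass (adjusted p = 0.139). It did not pass with median centring either (-1.41, adjusted p = 0.0854). TIE1 did not pass without replicate 1, 2 or 3 (adjusted p = 0.0668, 0.0652 and 0.0757) or with the deposited processed values (adjusted p = 0.0624). Of 22 leukocyte markers, CD74, which escorts class II molecules (-0.51 ± 0.05), and LYZ (-0.45 ± 0.11) fell and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.423). LYZ did not pass without replicate 1, 2 or 3 of 22 h (adjusted p = 0.115, 0.0573 and 0.154) or replicate 2 or 4 of 6 h (adjusted p = 0.0552 and 0.0605). FBLN1 (1.04 ± 0.07) alone rose among 15 fibroblast and smooth muscle markers and 0 fell. The median was -0.04 (1 and 0 adjusted over the list alone; camera adjusted p = 0.835). KRT19 (-0.76 ± 0.18) fell among 8 markers of surface epithelium (1 up and 1 down adjusted over the list alone; camera adjusted p = 0.963). It did not pass without replicate 2, 3 or 4 of 22 h (adjusted p = 0.0605, 0.119 and 0.0873) or replicate 1 or 4 of 6 h (adjusted p = 0.0575 and 0.0537). In limma's test with the adjustment over all probes, 0 of 13 oocyte markers and 0 of 7 erythrocyte markers changed, and the counts adjusted over the list alone were 0 as well (camera adjusted p = 0.915 and 0.941), while at an unadjusted p under 0.05 there were 1 oocyte marker up and 1 down and 0 erythrocyte markers. Both sets of markers were dim, so the lack of calls says little about these cells. The same holds for many leukocyte markers, such as CSF1R, CD3D and C1QC (mean log2 intensity 7.01, 7.39 and 7.41).

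Lists that did not pass camera at 22 h also included the unfolded protein response. Of its 20 genes, EDEM1 (0.30) and SEL1L (0.19) rose and HSPA5 (-0.96 ± 0.20) and HSP90B1 (-0.62 ± 0.10), both chaperones of the endoplasmic reticulum, fell (2 and 2 adjusted over the list alone; adjusted p = 0.915). HSPA5 did not pass without replicate 1, 3 or 4 of 22 h (adjusted p = 0.0563, 0.0856 and 0.0603). HSP90B1 did not pass without replicate 3 (adjusted p = 0.0517). Of 11 heat shock genes, HSPB1 (1.35 ± 0.11) and BAG3 (0.56) rose and HSPE1 (-0.67 ± 0.07) and HSPH1 (-0.93) fell (2 and 3 adjusted over the list alone; adjusted p = 0.452). Of 15 apoptosis genes, BCL2 (1.46 ± 0.10) and MCL1 (0.91 ± 0.06), which both protect from cell death, rose and BAX (-0.38), BID (-0.44) and BCL2L11 (-0.33), which promote it, fell (2 and 3 adjusted over the list alone; adjusted p = 0.915). The median of this list was -0.01 and its mean 0.05, and fry called it up (adjusted p = 0.00258). Of 20 matrix genes, PTX3, TNFAIP6 and SDC4 (2.19) rose and NID1 (-1.32) fell (3 and 1 adjusted over the list alone; adjusted p = 0.302). Of 26 inflammatory genes, NFKBIA, the inhibitor of NF-kB (0.74 ± 0.10), and IL6 (0.29 ± 0.06) rose and 0 fell (2 and 0 adjusted over the list alone; adjusted p = 0.0897). IL6 did not pass without replicate 2, 3 or 4 of 22 h (adjusted p = 0.0779, 0.11 and 0.0715). Of 20 genes of G protein and cAMP signalling, RGS2 and SPRY2 (1.29 ± 0.05) rose and ADORA2B (-0.61) fell (3 and 2 adjusted over the list alone; adjusted p = 0.452). Fry called the matrix (adjusted p = 0.033), inflammatory (adjusted p = 0.0156) and G protein lists (adjusted p = 0.00018) up. It did not call the unfolded protein response (adjusted p = 0.831) or heat shock (adjusted p = 0.189). At an unadjusted p under 0.05 in limma, 0 inflammatory genes, 0 angiogenic genes and 4 fibroblast markers were lower, and 0 endothelial markers, 1 leukocyte marker and 1 surface epithelium marker were higher, where the counts above are 0. The count of changed genes was 136 with median centring, 1025 in a fit of the 4 arrays of 22 h alone, 1473 without replicate 3 of 22 h, and 758 without the 3 arrays of the lowest background estimates.

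**Figure D2:**
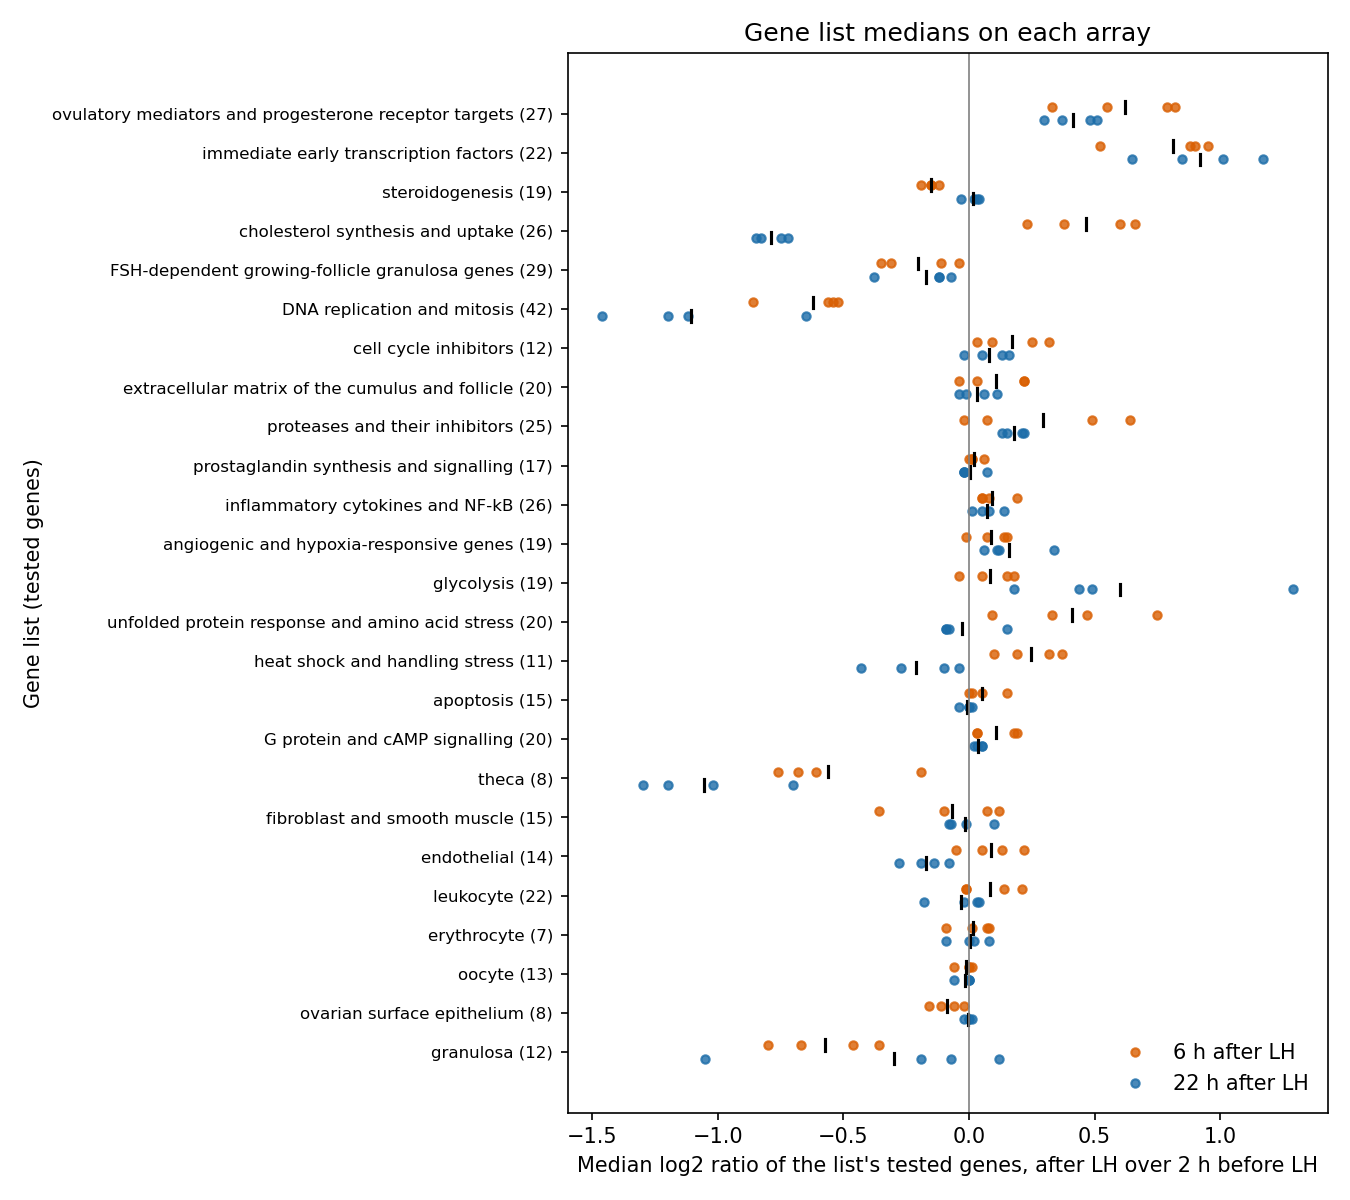
Median log2 ratio of post-LH over pre-LH RNA (horizontal axis) of each gene list (vertical axis, with the number of tested genes), with 1 point per array, orange at 6 h and blue at 22 h, and a black tick at the mean of 4 arrays. Medians of the cholesterol list lay between 0.23 and 0.66 at 6 h and between -0.85 and -0.72 at 22 h.

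The third comparison asked which changes differed between 6 h and 22 h, as the change at 22 h minus that at 6 h. PGR was lower at 22 h than at 6 h by 3.75 on the log2 scale (-3.75 ± 0.05, adjusted p = 9.57e-07), and PTGS2 was higher (5.17 ± 0.37), a value that rests on pre-LH levels not above background on the 6 h arrays. CYP51A1, a demethylase of cholesterol synthesis, had risen at 6 h (1.26) and fallen at 22 h (-2.57), a difference of -3.83 ± 0.18. In all, 2139 genes differed, 1091 higher and 1048 lower at 22 h, and 656 differed at least 2-fold. All 6 h arrays lay on one slide and all 22 h arrays on the other, so slide and time cannot be told apart in these differences, although pre-LH RNA was on every array. The pre-LH level could itself differ between slides. Mean log2 levels before LH on the 6 h and 22 h slides were 10.29 and 10.21 for PGR but 10.43 and 11.31 for MRO. After LH, VNN2 stood at 8.37 at 6 h and 13.66 at 22 h, further apart than its difference of 4.10 ± 0.09. The SE does not cover such shifts.

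Higher at 22 h than at 6 h by the largest amounts were GFRA1, a receptor of glial cell line-derived neurotrophic factor (5.28 ± 0.23), PTGS2, VNN2 (4.10 ± 0.09), HS3ST5, a heparan sulfate sulfotransferase (3.79 ± 0.18), NUDT11 (3.79 ± 0.29) and PLA2G4A (3.74 ± 0.19). The rank of PTGS2 is not known, because its pre-LH level was not above background on the 6 h arrays. Lower by the largest amounts were GPAT3 (-4.15 ± 0.14), CYP51A1, LRP8 (-3.82 ± 0.28), PGR, IL33, an alarm cytokine (-3.51 ± 0.34), and NCALD, a calcium sensor (-3.13 ± 0.14). Of the other genes set in advance, FSHR was higher (1.00 ± 0.19, adjusted p = 0.021) and CYP17A1 lower (-2.25 ± 0.12). LHCGR (-0.07 ± 0.13, adjusted p = 0.791), STAR (-0.34 ± 0.16, adjusted p = 0.246), CYP19A1 (-0.73 ± 0.38, adjusted p = 0.298) and CYP11A1 (-0.80 ± 0.29, adjusted p = 0.153) did not pass. For LHCGR this says little, since it was dim at both times, with mean log2 levels of 7.38 at 6 h and 7.30 at 22 h. FSHR did not pass without replicate 1 or 2 of 6 h or replicate 3 of 22 h (adjusted p = 0.068, 0.0757 and 0.0736). CYP11A1 passed without replicate 3 of 6 h (-1.06, adjusted p = 0.0485). LHCGR stood at 0.06 without replicate 3 of 6 h and at 0.01 without replicate 3 of 22 h. With the deposited processed values it passed at -0.47 (adjusted p = 0.0419).

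Cholesterol genes were lower at 22 h than at 6 h in 18 of 26 cases and higher in 1, LIPA (1.04) (18 and 2 adjusted over the list alone). The median was -1.18 (camera adjusted p = 1.22e-13; adjusted p = 0.159 with an estimated correlation). IDI1 differed by -2.90 ± 0.07 and NSDHL by -2.73 ± 0.11. DNA replication and mitosis genes were lower in 7 of 42 cases and higher in 0 (10 and 0 adjusted over the list alone; median -0.335; camera adjusted p = 9.03e-05; adjusted p = 0.624 with an estimated correlation). Among them were GINS1, a replication factor (-1.19 ± 0.13), and UBE2C, an enzyme of mitotic exit (-1.10 ± 0.19). UBE2C did not pass without replicate 2 of 6 h (adjusted p = 0.0517), and the list did not pass with fry (adjusted p = 0.0903). Genes of the unfolded protein response were lower in 7 of 20 cases and higher in 0 (9 and 0 adjusted over the list alone; median -0.44; camera adjusted p = 0.000188; adjusted p = 0.293 with an estimated correlation). HSPA5 was at -2.14 ± 0.28 and HERPUD1 at -1.08 ± 0.14. Glycolysis genes were higher in 4 of 19 cases and lower in 1, HK2 (-1.26) (8 and 1 adjusted over the list alone; median 0.46; camera adjusted p = 0.0139; adjusted p = 0.293 with an estimated correlation). The 4 were SLC16A3 (2.24 ± 0.23), PFKM (1.11 ± 0.12), ENO2 (0.71) and SLC2A3 (0.70). The list did not pass with median centring (adjusted p = 0.173) or without the 3 arrays of the lowest background estimates (adjusted p = 0.341).

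Heat shock genes differed between the times with a median of -0.29 (camera adjusted p = 0.0442; adjusted p = 0.293 with an estimated correlation). HSPB1 was higher (1.75 ± 0.16) and HSPE1 (-1.07 ± 0.09) and HSPH1 (-1.72) lower, out of 11 (1 and 3 adjusted over the list alone). The list did not pass without replicate 1 or 4 of 6 h (adjusted p = 0.0589 and 0.0739) or replicate 1, 3 or 4 of 22 h (adjusted p = 0.0938, 0.07 and 0.0525). Without both arrays of number 4 it was at adjusted p = 0.0741 and without the 3 arrays of the lowest background estimates at 0.143. Endothelial markers differed with a median of -0.22 (camera adjusted p = 0.0429; adjusted p = 0.624 with an estimated correlation). KDR (-1.32 ± 0.21), ENG (-0.50 ± 0.07) and PECAM1 (-0.33) were lower and CLDN5 (0.66) higher, out of 14 (4 and 1 adjusted over the list alone). The endothelial list did not pass without replicate 1 or 4 of 6 h (adjusted p = 0.0589 and 0.0607) or replicate 1, 2 or 3 of 22 h (adjusted p = 0.0805, 0.0839 and 0.07). Nor did it pass with the deposited processed values (adjusted p = 0.16), with fry (adjusted p = 0.0543) or without the 3 arrays of the lowest background estimates (adjusted p = 0.143). Without those arrays KDR stood at -0.865 (adjusted p = 0.164), and with median centring at -1.49 (adjusted p = 0.352). Leukocyte markers differed with a median of -0.11 (camera adjusted p = 0.0429; adjusted p = 0.577 with an estimated correlation), with CD74 (-0.38 ± 0.08) and LYZ (-0.62 ± 0.15) lower out of 22 (1 and 0 adjusted over the list alone). This list did not pass without replicate 1 or 3 of 6 h (adjusted p = 0.0589 and 0.0727) or replicate 1 or 3 of 22 h (adjusted p = 0.106 and 0.108). It did not pass with no background correction (adjusted p = 0.319), the deposited processed values (adjusted p = 0.305), no dye effect or median centring (adjusted p = 0.0969 in both), a background from negative controls (adjusted p = 0.0605) or fry (adjusted p = 0.0732). Without the 3 arrays of the lowest background estimates it was at adjusted p = 0.43. CD74 did not pass without any of 5 single arrays (adjusted p = 0.0555 to 0.0745) and LYZ without any of 7 (adjusted p = 0.0529 to 0.143). The other 18 lists did not pass camera in this comparison (adjusted p = 0.12 to 0.977). Of these, fry called apoptosis (adjusted p = 0.000148), G protein (0.0048), theca (0.00591), cell cycle inhibitor (0.0107) and protease lists (0.0368) down. It called prostaglandin (adjusted p = 0.0021), steroidogenesis (0.0125) and granulosa lists (0.0361) up. Among the 18 lists the ovulatory list had a median of -0.01 and a mean of 0.16, and the FSH-dependent list a median of 0.02 and a mean of -0.17. Granulosa markers, higher in 5 of 12 cases and lower in 0 (5 and 1 adjusted over the list alone; adjusted p = 0.178), passed as a list without replicate 4 of 22 h (adjusted p = 0.0285). At an unadjusted p under 0.05 in limma, 1 mitosis gene, 0 genes of the unfolded protein response and 0 leukocyte markers were higher and 2 granulosa markers lower, where the counts above are 0.

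**Figure D3:**
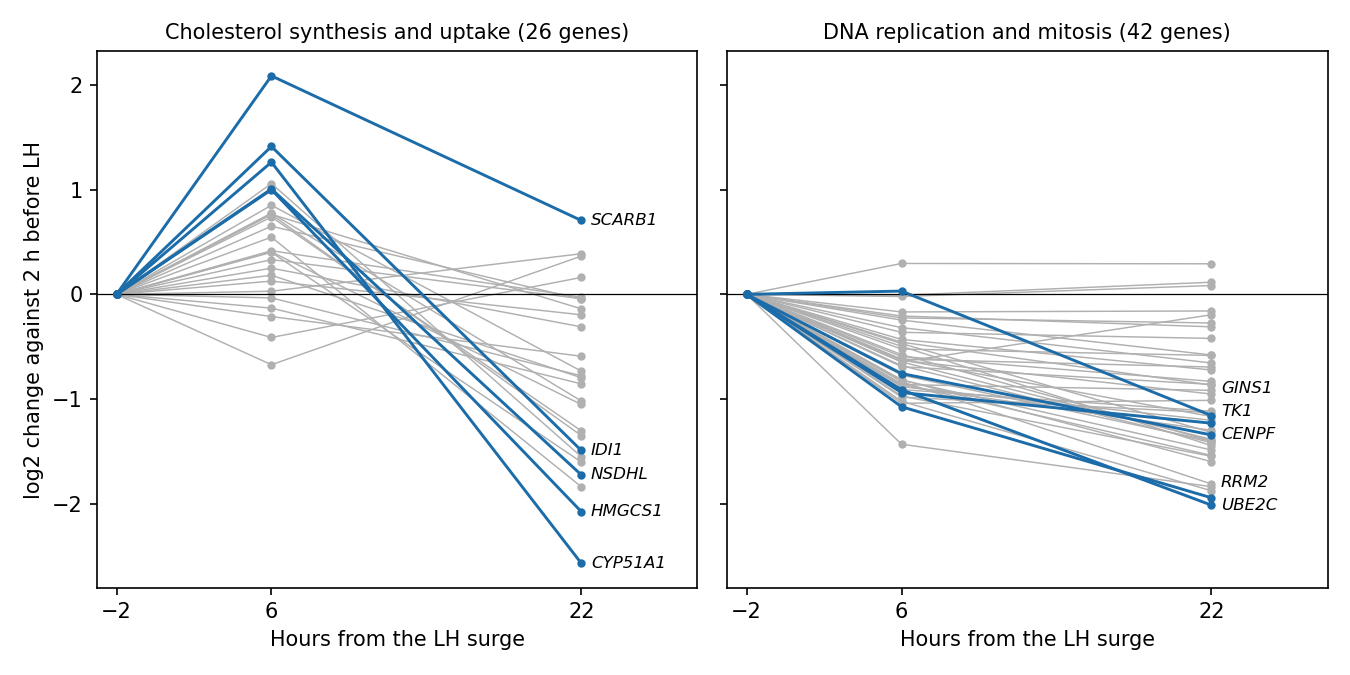
Log2 change against 2 h before LH (vertical axis) at 6 h and 22 h (horizontal axis, hours from the surge) for each tested gene of 2 lists, grey lines, with named genes in blue and every line starting at 0 before LH. The median of the cholesterol list was 0.48 at 6 h and -0.79 at 22 h, and that of the replication and mitosis list -0.645 and -1.14.

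By their calls in all comparisons, 1301 genes went back, 701 of them after a rise and 600 after a fall at 6 h, and 332 of these crossed their pre-LH level. Cholesterol enzymes such as IDI1 and CYP51A1 and the receptor PGR were among those that rose first and crossed. A further 116 genes went on in the direction of their first change, 66 up and 50 down. Late genes numbered 455, 265 up and 190 down, among them PLA2G4A. Across the 14138 genes the changes at 6 h and 22 h correlated with r = 0.434 and rho = 0.282. The same sign was seen in 56.8%; genes are not independent replicates. Unchanged groups were simulated against shared pre-LH RNA, whose share of the variance was set at 0.5 and not estimated. They gave r = 0.499, rho = 0.46 and 66.7% of equal sign in 100 simulations. The simulated r and share of equal signs follow from that setting, so they are no yardstick for the observed ones. The covariance was 0.0862 observed against 0.00495 simulated, a difference of 0.0813. With the pre-LH numbers split between the times, r was 0.411 and 0.413, and the covariance lay between 0.0778 and 0.0966. Both times shared 461 risen genes, against 159 for independent lists, and 698 fallen genes, against 192. A further 159 genes rose and then stood below the pre-LH level at 22 h, against 173. Another 173 fell and then stood above it, against 176. The independent counts leave out any shared pre-LH RNA and the simulated values leave out real changes, so the excess over either does not measure a shared effect. The counts of differing, returning, continuing and late genes were 22, 8, 0 and 9 with median centring. They were 1328, 735, 48 and 293 without replicate 1 of 6 h, 1187, 671, 40 and 266 without replicate 2 of 6 h, and 1291, 849, 66 and 229 without replicate 3 of 22 h. Without replicate 3 or 4 of 6 h, 60 and 73 genes went on, and 693 genes differed without the 3 arrays of the lowest background estimates and 1252 with a background from negative controls.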

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

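Of the tests in this part, those on theca markers at both times and the test of shared pre-LH RNA were chosen after the result was seen. Where 1 array lay far from the other 3 of its time, its log2 ratio was, at 22 h, 0.31 for CLDN5 on replicate 1, -2.12 for CYP11A1, -1.12 for GADD45G and 0.26 for SCARB1 on replicate 2, -0.94 for LHCGR on replicate 3 and -0.09 for HERPUD1 on replicate 4. At 6 h it was -0.79 for FSHR and -2.3 for SLC35G1 on replicate 2, 2.83 for LYPD1 and 0.93 for NFKBIA on replicate 3, and -1.22 for TK1 on replicate 4. Among list medians the distant arrays were, at 6 h, replicate 3 for immediate early factors (0.52) and for replication and mitosis (-0.86). At 22 h they were replicate 1 for the unfolded protein response (0.15) and apoptosis (-0.04), replicate 3 for surface epithelium (-0.02), and replicate 4 for FSH-dependent genes (-0.38), prostaglandin genes (0.07) and oocyte markers (-0.06). Chance alone gives about 1 in 20 groups, so 9.7 of the 194 gene groups tested, where 11 were seen, and 2.5 of the 50 list groups, where 8 were seen.

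The changes at 6 h and 22 h differed, by a test of the difference itself, for 2139 genes and for 7 lists: cholesterol (median -1.18), replication and mitosis (-0.335), glycolysis (0.463), the unfolded protein response (-0.438), heat shock (-0.285), endothelial markers (-0.215) and leukocyte markers (-0.114). With an estimated correlation none of the 7 passed camera. Among named genes, the changes against pre-LH passed in opposite directions and differed by -2.25 for CYP17A1, -3.83 for CYP51A1, -0.5 for ENG, 5.28 for GFRA1, -3.07 for HMGCS1, -1.24 for HSD17B7, -2.14 for HSPA5, 1.75 for HSPB1, -1.07 for HSPE1, -2.9 for IDI1, 1.96 for NR5A2, -2.73 for NSDHL, -3.75 for PGR and 2.24 for SLC16A3. Probes without a gene symbol, 18664 of the 38453 tested, entered the fit and the adjustment but not the counts of genes or the lists, and were called 2375 times at 6 h, 1813 times at 22 h and 1396 times between the times.

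For the counts at 6 h and at 22 h, 8 ways of turning the signs of 4 arrays are too few for a share under 0.05; 1 of 8, the real one, gave as many genes, with 3437 and 2878 real against 0 and 0 as the highest other. Between the times, 1 of the 35 splits of the 8 arrays, the real one, gave as many as 2139 genes, and the highest other, the split by dye orientation, gave 19, which excludes chance only if pairing is left aside. Of the 8 splits that part all pairs of equal number as the real one does, the highest other gave 0, and these 8 are too few for a share under 0.05. The other 27 keep at least 1 pair together. Slide and time cannot be told apart in any of these splits.

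Cholesterol genes were high at 6 h and low at 22 h, with medians of 0.481 and -0.787, although with an estimated correlation the list did not pass (adjusted p = 0.148 at 6 h and 0.116 at 22 h). Against an intensity-dependent error of the normalization, the central 95% of 10000 lists of equally bright random genes reached only 0.131 at 6 h and only -0.174 at 22 h. Against an effect of 1 dye or of single arrays, the lowest array median was 0.228 at 6 h and the highest was -0.72 at 22 h, in both dye orientations. The same array medians argue against a slide effect common to both channels or to 1 dye, since each ratio lies within an array. An effect of slide on the size of the ratios, and follicle size, go with time in this design. Both stay open and were not tested apart from it.

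The median of the theca markers was low at both times, although with an estimated correlation the list did not pass (adjusted p = 0.345 at 6 h and 0.231 at 22 h), 4 of 8 fell at 6 h, and PTCH1 rose at 22 h. At 6 h a lower share of theca cells as the only cause is argued against by CYP17A1, which was higher (0.362), although in 8 alternatives it stood at 0.279 to 0.377 and no longer passed (adjusted p = 0.0539 to 0.798), among them median centring and the fits without replicate 2, 3 or 4 of 6 h. At 22 h, 6 of the 8 tested theca markers fell, among them CYP17A1, and a lower share of theca cells may be a part of this; regulation within theca cells stays open as well. Fibroblast and smooth muscle markers had a median 1.12 above that of the theca markers at 22 h (exact permutation p = 0.00142 over 490314 regroupings of the genes, which are not independent). This goes against a lower share of all cells other than granulosa cells alike only if those markers come from such cells. Which cells made them was not tested, and the permutation compares 2 lists, not shares of cells. Some of these markers measure change poorly. COL1A2, ACTA2 and COL3A1 were among the brightest genes (mean log2 intensity 15.1, 15.2 and 15.3), in cells that the labels describe as mainly granulosa cells. PDGFRB (7.22) and TAGLN (7.31) were dim. Endothelial markers (5 of 14 fell, 0 rose in limma) went the way of the theca markers. Of 22 leukocyte markers only CD74 and LYZ did, and that list did not pass (median -0.06, camera adjusted p = 0.423). Many leukocyte markers were as dim as the oocyte markers, such as CSF1R (7.01), CD3D (7.39) and C1QC (7.41). The lack of calls among them therefore says little about leukocytes. A lower share of some of these cells stays open.

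Arrays of the same replicate number were mostly alike across the slides, but number 4 correlated more with another number (0.33) than with its own (0.22) in log2 ratios, as did number 1 in the post-LH channel (0.67 against 0.59). Equal numbers also share the dye orientation, which was not taken out of these r. With the dye effect in the model, the consensus correlation of log2 ratios within numbers was only 0.0539. In the pre-LH channel all numbers correlated most with their own, with r of 0.9, 0.92, 0.95 and 0.98. The highest r with another number was 0.73, 0.75, 0.72 and -0.83 there. Pre-LH RNA shared by number as the only cause is argued against by the post-LH channel, whose differences correlated across slides with r of at least 0.314. Array position on the slide, which is the same for both arrays of a number, goes with the correlation on 58 control probes, whose lower mean r was 0.589, and is a candidate explanation. Control probes may also pick up RNA of the sample, and sharing of pre-LH RNA as a part of the cause stays open. No biological explanation was tested for this pattern.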

How the results depend on the processing

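The tests with a background from negative controls, with median pixel intensities, without both arrays of number 4 and without the 3 arrays of the lowest normexp backgrounds were chosen after the result was seen. Over all alternatives, 2273 values of named genes kept direction and side of the threshold, 217 kept direction but no longer passed, 4 came to pass and 5 changed sign. Of the 217, 99 had a change as large as before or larger. For lists 1327 stayed on their side of the threshold, 67 no longer passed, 30 came to pass and 1 reversed. Of the counts and correlations 91 stayed close, 37 counts were lower by more than 1.5 times and 8 correlations moved. With median centring in place of loess, 85 genes changed at 6 h, 136 at 22 h and 22 differed between the times, 8 went back, 0 went on and 9 were late, the shared r was 0.445 and FSHR at 22 h stood at -0.0316; 89.4% and 73.5% of the genes changed at 6 h and 22 h then rose, against 47.4% and 47.9%, and 97 named-gene values no longer passed, 46 of them with a change as large as before or larger; the cause was not tested. With adjusted p and 2-fold, counts were 594, 596 and 656, and with adjusted p under 0.01 they were 1829, 1481 and 895, with about 5.3e+02 back, 30 on and 144 late, since fewer genes can pass a stricter rule. A fit of the arrays of 1 time alone gave 1025 genes at 22 h but 3679 at 6 h; the cause was not tested. A background from negative controls gave 2103 genes at 6 h and 1252 between the times; the cause was not tested. Without the 3 arrays of the lowest normexp backgrounds, 758 genes changed at 22 h, 64% of them up, 693 differed between the times, FSHR at 22 h was -0.209, 28 named-gene values no longer passed, with KDR at -0.729 and HSPA5 at -0.58 at 22 h, and 8 lists no longer passed, among them angiogenic genes at 22 h (median 0.129, adjusted p = 0.0754) and glycolysis between the times (median 0.205, adjusted p = 0.341); the cause was not tested. In the fit without those 3 arrays, 2 other lists came to pass. With pre-LH numbers split between the times the shared r was 0.413 and 0.411. Leaving out 1 array at a time gave 1933 to 3765 genes at 6 h, 1473 to 2836 at 22 h and 1187 to 2052 between the times, 671 to 1332 back, 40 to 152 on, 229 to 400 late, a shared r of 0.419 to 0.444, FSHR at 22 h from -0.0659 to 0.273 and LHCGR between the times from -0.135 to 0.0599, with 0.0112 without replicate 3 of 22 h; neither gene had passed. An estimated correlation ended all 28 list calls. With fry in place of camera 3 lists no longer passed and 20 came to pass, and fry called apoptosis at 22 h up (median -0.0111, adjusted p = 0.00258) where camera's direction was down without passing, since the tests ask different questions. The number as a random block gave 3419, 2859 and 2258 genes and changed no call of a named gene or list. Median spot intensities of 150 to 192 in Cy3 stood over negative control medians of 105 to 145, which limits what can be said of dim probes.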

Other observations

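Genes were also grouped by the stem of their symbols, a rule chosen after the data had been seen, which gave 162 families of at least 10 tested genes. Camera called 1 family at 6 h, 5 at 22 h and 1 between the times, and 0 in each comparison with an estimated correlation (lowest adjusted p = 0.826, 0.919 and 0.912). At 6 h, 10 of 14 RAD genes fell and 0 rose (median -0.42, adjusted p = 0.000677), among them RAD21 (-1.36) of the cohesin complex and the repair genes RAD51B (-0.96), RAD54B (-0.96) and RAD50 (-0.73). At 22 h, 6 RAD genes fell (median -0.33, adjusted p = 0.0304), as did 7 of 12 ALG genes of N-glycan assembly (median -0.39, adjusted p = 0.01; ALG6 -0.87, ALG8 -0.63, ALG5 -0.46) and 5 of 10 SRSF splicing factors (median -0.33, adjusted p = 0.0166; SRSF10 -0.59, SRSF2 -0.58). Histone demethylases of the KDM family rose in 7 of 13 cases (median 0.30, adjusted p = 0.01; KDM3A 0.71, KDM1A 0.67, KDM5B 0.60) and VPS genes of vesicle sorting in 7 of 31 (median 0.15, adjusted p = 0.0304; VPS35 0.91, VPS16 0.82). Between the times 3 SRSF genes were lower at 22 h (median -0.33, adjusted p = 0.0313). The genes named here were chosen after their values were seen.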
